A study of Homo sapiens with 4 samples.

How the data were processed

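Expression was measured by RNA sequencing in 4 human pancreatic libraries, 1 per group. Tissue left over from islet isolation, enriched for exocrine cells, was cultured for 48 h in 8% oxygen, and cells bright for the BMP receptor ALK3 (gene BMPR1A) and positive for the purinergic receptor P2RY1 were sorted from it by flow cytometry. The groups were these sorted cells untreated, the sorted cells after BMP7 at 100 ng/ml, the sorted cells differentiated after BMP7 was removed, at 21% oxygen, and islets. Per the labels' protocols, RNA of 3 non-diabetic donors was pooled before each library was made, and the islets came from the same donors. By the same protocols, RNA was taken from about 150000 cells and the RNA input was 8 ng. The libraries were made with a stranded total RNA kit that removes ribosomal RNA and read as 50-nt paired ends. Whether the untreated cells were cultured after the sort, for how long the BMP7-treated and differentiated cells were, and the oxygen level during BMP7 treatment are not given in the sources used here. Each difference after BMP7 or after differentiation is therefore confounded with time in culture, and may be with oxygen.

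The authors deposited 1 table per library of normalized RPKM (reads per kilobase of transcript, scaled to library depth), per the file headers. TopHat2 2.1.0, Bowtie2 and the genome build hg38 are named in the submitters' processing notes. The read counter, its annotation, its use of strand and the further normalization are not given in the sources used here. The 4 tables hold the same 19797 rows in the same order. Left out were 28 rows whose gene name had become a date number, and 48 rows (XIST, TSIX and Y-linked genes) kept out for privacy. A repeat of a gene name was kept as a row of its own (21 rows), which left 19721 rows, 1160 of them at 0 in all libraries.

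The depth was worked out from the values. Multiplied by the gene's exon length in GENCODE release 29 and divided by a constant per library, the RPKM values came out whole within 0.01 reads in all 4 libraries for 15552 of the 17616 expressed genes with a length (88.3%). The smallest whole length that gave whole reads was used for 2727 more genes, so that reads were had for 98.5% of 18561 expressed genes; a smallest length can make such read numbers too low, and their intervals then too wide. In genes matched by exon length there were 30837601 reads in the untreated, 39242968 in the BMP7, 15066795 in the differentiated and 23796181 in the islet library. The constants correspond to RPKM denominators of 304236524, 380777124, 95147889 and 190316483 reads, far above these read numbers and not in proportion to them. Whether reads outside these genes or the further normalization account for this cannot be told, so the scale may not be that of plain RPKM. The reads were used for 95% exact (Clopper-Pearson, conditional binomial) intervals of the ratio of 2 libraries, and for a floor of 3 reads per library against which a fold for a gene at 0 was computed. Both cover the counting error of reads only. Reads copied by PCR are not independent molecules, so the intervals can be too narrow.

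Before the data were examined, 5 comparisons, 28 gene lists and the alternatives were fixed. A gene was compared where it had at least 1 RPKM in 1 of the 2 libraries, and its difference was log2((RPKM + 1)/(RPKM + 1)), a scale that understates the change of low genes. Genes at least 2-fold apart on that scale were counted. Folds given for single genes are plain ratios of RPKM without the pseudocount. With 1 library per group there is no replicate check, no test was made and no p-value is given. Each difference is between 2 libraries. For each list with at least 5 compared members the median log2 difference was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list is said to stand apart at or below percentile 2.5 or at or above percentile 97.5, as a description of these libraries. The lists were sort markers, BMP target genes, BMP receptors and ligands, TGF-beta target genes, pancreatic progenitor genes, endocrine lineage transcription factors, islet hormone and secretory granule genes, beta cell glucose sensing and identity genes, acinar genes, ductal genes, epithelial junction genes, mesenchymal transition genes, stellate and fibroblast genes, endothelial, immune cell, Schwann cell and red blood cell genes, cell cycle genes, hypoxia-induced genes, immediate early and heat shock genes, NF-kB and cytokine genes, unfolded protein response genes, cholesterol synthesis genes, Notch pathway genes, YAP target genes, pluripotency genes, mitochondrially encoded genes and cytosolic ribosomal protein genes. Some genes stand in more than 1 list. The text names, for each comparison, from the 12 genes with the highest and the 12 with the lowest difference among genes with at least 5 RPKM in 1 of the 2 libraries (leaving out uncharacterised, noncoding and pseudogene names), and list members with at least 1 RPKM in 1 of the 2. Genes of cell type lists and sort markers below 1 RPKM are named outside this rule to show their low level, as are the other genes said to be so.

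The alternatives were a pseudocount of 0.1 or 5, a minimum of 5 RPKM or no minimum, median-of-ratios, upper quartile or quantile scaling of the 4 libraries, totals without mitochondrial, acinar and hormone genes, a threshold of 4-fold, and random lists not matched on expression. The calculation was tested on simulated data. For the BMP7 comparison, Poisson reads were drawn for 5427 genes at the measured means and depths, 200 of them changed. At least 2-fold apart on the scale with the pseudocount were 67 of 67 genes changed by 8-fold, 59 of 66 changed by 4-fold, 0 of 67 changed by 2-fold and 0 of 4817 unchanged genes. The pseudocount puts a ratio of 2 below the threshold, so genes changed by 2-fold could be found only through counting noise. In the 4 other comparisons 51 to 55 of 66 genes changed by 4-fold were found, and the other numbers of genes found were the same, with 0 unchanged genes. The intervals held the simulated fold for 94.7% of genes. Of 200 unchanged lists of 15 genes 3.50% stood apart, up to 5.50% in differentiated against untreated cells. The draws followed the counting model that the intervals assume, and the lists were of genes picked at random. These shares therefore leave out variation between libraries and genes that vary together, and are no error rate for the fixed lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Gene positions are those of GENCODE release 29 on GRCh38 (hg38), counted from 1.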

Results

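RNA of human pancreatic cells bright for the BMP receptor ALK3 and positive for the purinergic receptor P2RY1 was sequenced before and after treatment with BMP7, a bone morphogenetic protein, and after differentiation, and set beside islets of the same 3 donors. The series asks how such cells of exocrine tissue respond to BMP7 and how far they resemble islet cells once differentiated. Each of the 4 groups is 1 library of pooled RNA, so no difference below has a replicate check. Time in culture after the sort is not recorded and cannot be separated from BMP7 treatment or differentiation. Genes with at least 1 RPKM numbered 4929 in the untreated, 4897 in the BMP7, 5425 in the differentiated and 5430 in the islet library. Mitochondrially encoded genes took 25.8%, 21.3%, 64.5% and 25.9% of the summed RPKM in the same order. The lists of mitochondrially encoded and of ribosomal protein genes were fixed as signs of RNA quality. Whether RNA quality differed in the differentiated library, and bears on its differences below, was not tested.

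The genes of the sort markers were compared first. BMPR1A, which encodes ALK3, had 0.416, 0.506, 0.664 and 0.482 RPKM in untreated, BMP7-treated and differentiated cells and islets. P2RY1 had 0.230, 0.0471, 0.0374 and 2.42 RPKM, so its transcript was 10.5-fold (9.56 to 11.6) higher in islets than in the untreated cells sorted for the protein. Of the markers of other cell types that the tissue could hold, no endothelial gene reached 1 RPKM in a sorted library, against 4 in islets, where PLVAP had 6.06 RPKM. Among immune cell genes, LYZ, which also stands in the list of gland secretory genes below, had 106, 26.6, 106 and 1.11 RPKM. CD68 had 3.62, 3.14, 5.80 and 5.49 RPKM and CD74 had 5.88, 7.26, 5.59 and 1.34 RPKM. Below the 1 RPKM minimum, and so outside the naming rule, several leukocyte genes were higher in differentiated than in untreated cells. The pan-leukocyte gene PTPRC had 0.00550, 0.0411, 0.114 and 0.00690 RPKM, and the myeloid genes CD14, ITGAX and TYROBP had 0.0436, 0.0682, 0.942 and 0.426 RPKM, 0.0269, 0.0598, 0.316 and 0.0475 RPKM and 0.0616, 0.423, 0.695 and 0.122 RPKM. ERBB3, with 1.23, 1.73, 3.69 and 0.228 RPKM, was the only Schwann cell gene to reach 1 RPKM, while the Schwann cell factor SOX10 stayed at or below 0.0304 RPKM. No red blood cell gene and no pluripotency gene reached 1 RPKM in any library, and POU5F1 was at most 0.536 RPKM.

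In BMP7-treated against untreated cells, the comparison that asks for the response to BMP7, TGF-beta target genes and several genes of the extracellular matrix were higher. The medians of the acinar and ductal lists were lower. TGFBI, a matrix protein induced by TGF-beta (chromosome 5, 136028895 to 136063818), was 26.6-fold (25.7 to 27.6) higher, at 34.5 against 1.29 RPKM. The mucin gene MUC6 (chromosome 11, 1012821 to 1036706) was 9.19-fold (9.13 to 9.26) lower, at 26.5 against 244 RPKM. Of 5442 genes compared, 93 were at least 2-fold higher and 79 at least 2-fold lower, and 13 gene lists stood apart.

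The largest difference upward was that of FDCSP, a small secreted peptide (chromosome 4, 70226071 to 70235252), which was 54.1-fold (44.9 to 65.9) higher after BMP7. The protease inhibitor SERPINA1 was 8.46-fold (8.30 to 8.62) higher. COL5A1, FBN1 (fibrillin), BGN, POSTN and TNC, all of the matrix, were 7.01-fold, 7.41-fold, 6.25-fold, 5.21-fold and 5.23-fold higher, whereas NID2, of the basement membrane, was 10.8-fold (10.3 to 11.4) lower. The protease gene MMP7 was 5.33-fold (5.26 to 5.41) higher, at 185 RPKM. Of the 15 TGF-beta target genes, 9 were at least 2-fold higher and 0 lower (median log2 difference 1.41, percentile 100). They included CTGF, PMEPA1, COL1A1 and SKIL, at 5.03-fold, 6.15-fold, 4.30-fold and 6.80-fold. Of the 9 BMP target genes compared, 3 were at least 2-fold higher and 0 lower (median log2 difference 0.66, percentile 100). The direct targets ID1 and ID3 were 29.1-fold higher (no interval, as no reads were recovered for ID1, nor for NKX6-1, GCG and PAX6) and 8.65-fold (7.29 to 10.3) higher, reaching 1.24 and 2.26 RPKM, and the antagonist GREM1 had 11.2 against 16.7 RPKM. Stellate and fibroblast genes (5 of 16 at least 2-fold higher, 0 lower, median log2 difference 0.57, percentile 100) and mesenchymal transition genes (4 of 11 higher, 0 lower, median log2 difference 0.41, percentile 99.97) stood apart upward, with CDH2 3.89-fold and FN1 2.95-fold higher. Within the fibroblast list the members went apart. RGS5, a pericyte gene below the 1 RPKM minimum and so outside the naming rule, had 0.858 against 0.102 RPKM, COL6A1 had 17.8 against 20.3 RPKM, and DCN was 3.48-fold (3.30 to 3.66) lower.

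Smaller medians above the random lists were those of BMP receptors and ligands (0 of 8 at least 2-fold higher, median log2 difference 0.35, percentile 99.76), Notch pathway genes (0 of 5, median log2 difference 0.36, percentile 99.55), hypoxia-induced genes (2 of 13 higher and 1 lower, median log2 difference 0.20, percentile 98.91) and immediate early and heat shock genes (2 of 12, median log2 difference 0.20, percentile 99.41). Among these, the regulator of glycolysis PFKFB3 was 4.45-fold higher and ADM 4.50-fold lower. Without the RPKM minimum the BMP receptor, Notch and immediate early lists no longer stood apart, and with a minimum of 5 RPKM the hypoxia list did not.

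Lower after BMP7 were CCL11, an eosinophil chemokine, at 251-fold (184 to 352) lower, IGFBP5 at 18.8-fold (18.4 to 19.2) lower, TFPI2 at 27.1-fold (24.6 to 29.999) lower and the peptidase DPP4 at 28.5-fold (26.1 to 31.2) lower. The epithelial defence genes DMBT1, LCN2, PIGR and REG3A were 11.5-fold, 7.91-fold, 5.89-fold and 4.97-fold lower. Acinar genes, which make digestive enzymes, stood apart downward, with 5 of 11 at least 2-fold lower and 0 higher (median log2 difference -0.89, percentile 0). CPA1 was 45.9-fold (35.3 to 60.9) lower, whereas PRSS2 had 51.2 against 37.7 RPKM. Ductal genes (3 of 22 lower, 1 higher, median log2 difference -0.48, percentile 0) included KRT18 and KRT8 at 3.0000-fold and 2.45-fold lower, and MMP7 as the member that was higher. Cell cycle genes had a lower median with no member at least 2-fold apart among 12 (median log2 difference -0.30, percentile 0.07). MKI67, for instance, had 2.29 against 3.41 RPKM. Cholesterol synthesis genes (1 of 14 lower, median log2 difference -0.36, percentile 0.01) included SCD at 2.93-fold (2.89 to 2.96) lower. Mitochondrially encoded genes had median log2 difference -0.39, percentile 0.4, with no member 2-fold apart. Under quantile normalization that median was 0. The lists that did not stand apart were progenitor genes (-0.03), hormone and granule genes (-0.19), epithelial junction genes (-0.13), NF-kB and cytokine genes (0.09), unfolded protein response genes (-0.04), YAP targets (0.13) and ribosomal protein genes (-0.14).

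**Figure D1:**
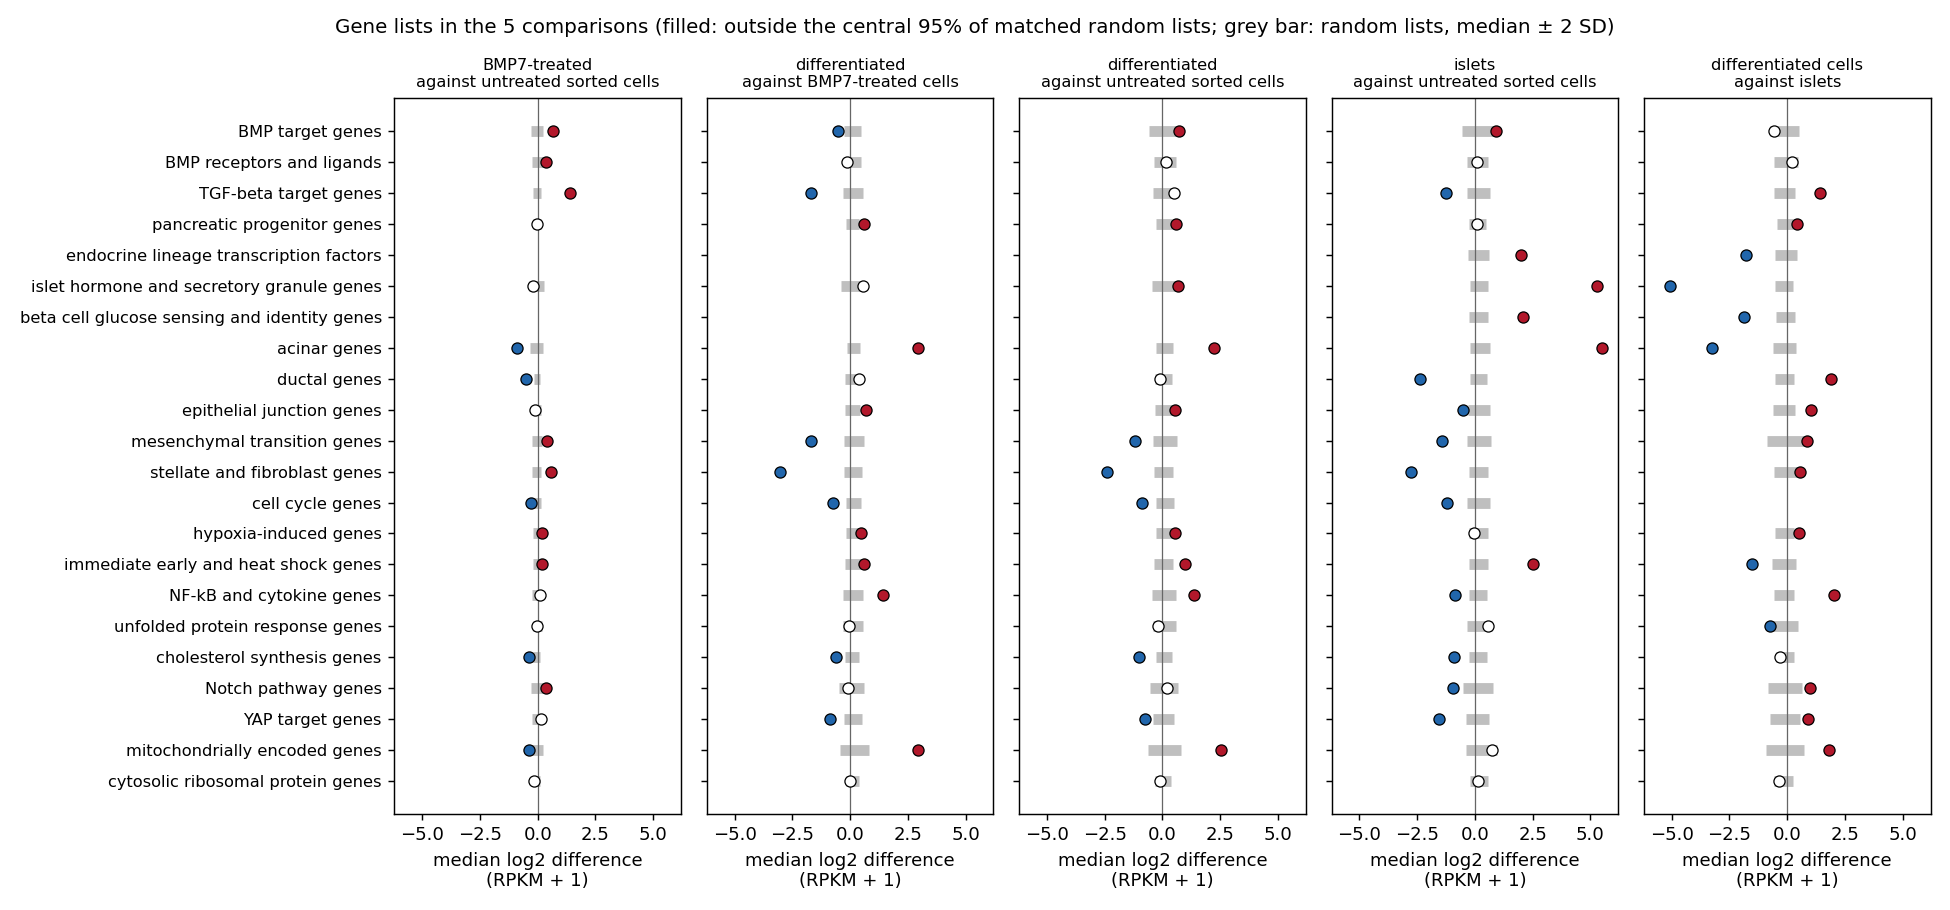
Median log2 difference (RPKM + 1) of each gene list with at least 5 compared members (rows) in the 5 comparisons (panels), as points filled red where the list stood apart upward, blue downward and white where it did not. Grey bars are the random lists, median ± 2 SD. TGF-beta targets lie at 1.41 in the BMP7 panel and at -1.67 in the differentiated against BMP7 panel. The mitochondrial medians of the differentiated library against BMP7-treated and untreated cells, 2.95 and 2.55, were 0 under quantile normalization.

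Differentiated cells were next set against the BMP7-treated cells they follow. Acinar enzyme genes, inflammatory genes and mitochondrially encoded genes were higher in the differentiated library, and genes of fibroblasts and matrix were lower. CTRB1, a chymotrypsinogen gene (chromosome 16, 75219000 to 75226338), was 167-fold (147 to 189) higher, at 113 against 0.680 RPKM. POSTN, the matrix protein periostin (chromosome 13, 37562583 to 37598844), was 51.7-fold (48.7 to 54.98) lower, at 2.07 against 107 RPKM. Of 6086 genes compared, 299 were at least 2-fold higher and 229 lower, so that 56.6% of these were higher, against 44.6% under upper quartile scaling and 40.3% with totals that leave out mitochondrial, acinar and hormone genes. The median log2 difference of all compared genes moved with scaling, from 0.11 to -0.10 with those totals, from 0.08 to -0.14 for differentiated against untreated cells and from 0.14 to -0.03 for islets against untreated cells, so list medians are best read against the random lists, which carry the same shift.

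Of 22 acinar genes, 20 were at least 2-fold higher and 0 lower (median log2 difference 2.95, percentile 100). CPA1 and PLA2G1B were 556-fold (429 to 735) higher and 108-fold (75.1 to 161) higher, from levels of 0.0512 and 0.123 RPKM after BMP7. Reads of CTRB1 and CTRB2, and of PRSS1, PRSS2 and PRSS3, come from near-identical copies and may have been split between them. Beside this, mitochondrially encoded genes made up 64.5% of the summed RPKM of this library and 32.02% of its recovered reads, and all 13 mitochondrially encoded genes were at least 2-fold higher as deposited (median log2 difference 2.95, percentile 100), and MT-CO1 was 10.3-fold (10.2 to 10.3) higher. Under quantile normalization the median of the mitochondrial list was 0 and MT-ND2, MT-ATP8, MT-CO3 and MT-CYB turned lower. The nuclear copies MTRNR2L8, MTRNR2L1, MTRNR2L12 and MTRNR2L6, near-identical to mitochondrial ribosomal RNA, were 15.1-fold, 18.96-fold, 12.6-fold and 17.7-fold higher and cannot be told from it by such reads.

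NF-kB and cytokine genes stood apart upward (14 of 16 higher, 0 lower, median log2 difference 1.44, percentile 99.99). CXCL8 and CXCL2, neutrophil chemokines, were 4.11-fold and 5.63-fold higher, IL1B 16.7-fold (14.7 to 19.1) higher and LCN2 5.55-fold higher. The leukocyte genes given above, such as CD14 at 0.942 against 0.0682 RPKM, were higher in the same library, and whether leukocytes contributed to this list was not tested. REG3A, an antimicrobial lectin, was 14.6-fold (14.2 to 15.1) higher. Progenitor genes (3 of 15 higher, 0 lower, median log2 difference 0.61, percentile 99.99) included the transcription factors NKX6-1 at 6.96-fold higher, ONECUT1 at 4.93-fold and NR5A2 at 3.09-fold. Epithelial junction genes (2 of 16, median log2 difference 0.70, percentile 99.96) included OCLN at 2.77-fold and CGN at 2.97-fold. Hypoxia-induced genes (5 of 18 higher, 1 lower, median log2 difference 0.46, percentile 99.85) included VEGFA and NDRG1 at 2.97-fold and 4.64-fold higher, and LOX 5.09-fold lower, although the differentiated cells were kept at 21% oxygen. Immediate early and heat shock genes (4 of 15, median log2 difference 0.58, percentile 99.57) included FOS at 17.8-fold (15.7 to 20.2) higher and EGR1 at 7.11-fold.

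Stellate and fibroblast genes were lower in 14 of 15 members, with 0 higher (median log2 difference -3.02, percentile 0). ACTA2 (smooth muscle actin), COL1A1, COL1A2, SPARC and COL3A1 were 35.5-fold, 19.1-fold, 15.7-fold, 15.9-fold and 14.03-fold lower. Outside the list, COL4A1, COL11A1, THBS2, FBN1, SULF1 and COL5A2 were 22.5-fold, 48.7-fold, 19.99-fold, 25.9-fold, 35.4-fold and 20.5-fold lower. All 10 mesenchymal transition genes compared were at least 2-fold lower (median log2 difference -1.71, percentile 0), with SNAI2 at 9.96-fold and CDH2 at 15.8-fold. TGF-beta targets were lower in 8 of 15 and higher in 1 (median log2 difference -1.67, percentile 0), the higher member being ITGB6 at 2.69-fold. BMP targets were lower in 2 of 9 and higher in 0 (median log2 difference -0.53, percentile 0.14), and ID1 and ID3 had 0.557 and 0.561 RPKM, 2.23-fold and 4.03-fold lower. YAP targets (5 of 11 lower, 1 higher, median log2 difference -0.85, percentile 0), cell cycle genes (4 of 11 lower, 0 higher, median log2 difference -0.73, percentile 0.01) and cholesterol synthesis genes (2 of 13 lower, 0 higher, median log2 difference -0.61, percentile 0) stood apart downward. CRIM1, TOP2A and SCD were 5.95-fold, 7.70-fold and 4.65-fold lower. Not apart were BMP receptors and ligands (-0.12), hormone and granule genes (0.55, percentile 96.78), ductal genes (0.37), unfolded protein response genes (-0.06), Notch genes (-0.08) and ribosomal protein genes (-0.000967).

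Against the untreated cells, the differentiated library had higher complement, acinar and mitochondrial transcripts and lower fibroblast transcripts. CFB, complement factor B (chromosome 6, 31945650 to 31952084), was 24.01-fold (23.6 to 24.5) higher, at 202 against 8.43 RPKM, and C3 (chromosome 19, 6677704 to 6730562) was 14.8-fold (14.6 to 15.01) higher. IGFBP5 (chromosome 2, 216672105 to 216695525) was 79.2-fold (72.5 to 86.7) lower, at 0.803 against 63.6 RPKM. CCL11, with 24.4 RPKM in untreated cells, had no read in the differentiated library. It was 836-fold lower against the floor of 3 reads, and at least 680-fold lower by its interval. Of 6240 genes, 433 were at least 2-fold higher and 286 lower, 60.2% of them higher. That share was 47.98% under upper quartile scaling and 43% with totals that leave out mitochondrial, acinar and hormone genes.

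Acinar genes were at least 2-fold higher in 19 of 22 members and lower in 0 (median log2 difference 2.25, percentile 100), with CTRB1 and CTRB2 at 31.3-fold and 39.8-fold and AMY2A at 1.30-fold. The mitochondrial list was higher in all 13 members as deposited (median log2 difference 2.55, percentile 100), with a median of 0 and MT-ND2, MT-ATP8 and MT-CO3 turned lower under quantile normalization. ALB and the heparan sulfate proteoglycan gene SDC4 were 12.2-fold (11.95 to 12.5) higher and 11.1-fold (10.8 to 11.5) higher. Hormone and granule genes stood apart upward (2 of 6 compared members higher, median log2 difference 0.69, percentile 98.56), a call lost without the RPKM minimum. INS was 3.86-fold (3.39 to 4.39) higher, at 7.06 against 1.83 RPKM, with 5.51 RPKM after BMP7. CHGA was 4.30-fold (3.85 to 4.81) higher, whereas IAPP was 3.76-fold (2.86 to 5.03) lower. Progenitor genes (4 of 15 higher, 0 lower, median log2 difference 0.59, percentile 99.91) included NKX6-1 at 6.72-fold higher and PDX1 at 1.08 against 0.593 RPKM. Of the endocrine transcription factors only HHEX reached 1 RPKM. Named outside the rule for their role in beta cells, MAFA, PAX6 and NKX2-2 had 0.210, 0.531 and 0.0251 RPKM in differentiated and 0.0158, 0.0173 and 0.00314 RPKM in untreated cells. NEUROG3, which starts endocrine development, was listed at 0 in all 4 libraries.

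BMP targets stood apart upward (1 of 5 higher, 1 lower, median log2 difference 0.73, percentile 98.39), a call lost with a pseudocount of 0.1 or 5 and without the RPKM minimum. SKIL was 10.5-fold higher and GREM1 41.3-fold (38.1 to 45.01) lower. Also upward were NF-kB and cytokine genes (13 of 17, median log2 difference 1.36, percentile 99.97), immediate early and heat shock genes (7 of 15, median log2 difference 0.97, percentile 100), hypoxia-induced genes (6 of 19, median log2 difference 0.56, percentile 99.92) and epithelial junction genes (4 of 16, median log2 difference 0.55, percentile 99.26). Downward were stellate and fibroblast genes (14 of 16, median log2 difference -2.40, percentile 0), mesenchymal transition genes (7 of 11, median log2 difference -1.20, percentile 0), cell cycle genes (5 of 12, median log2 difference -0.89, percentile 0), cholesterol synthesis genes (7 of 14, median log2 difference -1.001, percentile 0) and YAP targets (4 of 10 lower, 1 higher, median log2 difference -0.74, percentile 0.02). Among single genes, the small heat shock protein HSPB6, the stromal receptor CD248 and the hyaluronan synthase HAS2 were 47.2-fold (37.8 to 59.6) lower, 69.3-fold (49.8 to 99.6) lower and 33.1-fold (27.9 to 39.5) lower. MUC6 and DMBT1 were 18.1-fold and 31.8-fold lower. TGF-beta targets went both ways (5 higher and 4 lower of 13, median log2 difference 0.49, percentile 94.72), with ITGB6 10.4-fold higher and ACTA2 18.7-fold lower. Ductal genes (-0.10), BMP receptors and ligands (0.17), Notch genes (0.21), unfolded protein response genes (-0.18) and ribosomal protein genes (-0.09) did not stand apart.

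**Figure D2:**
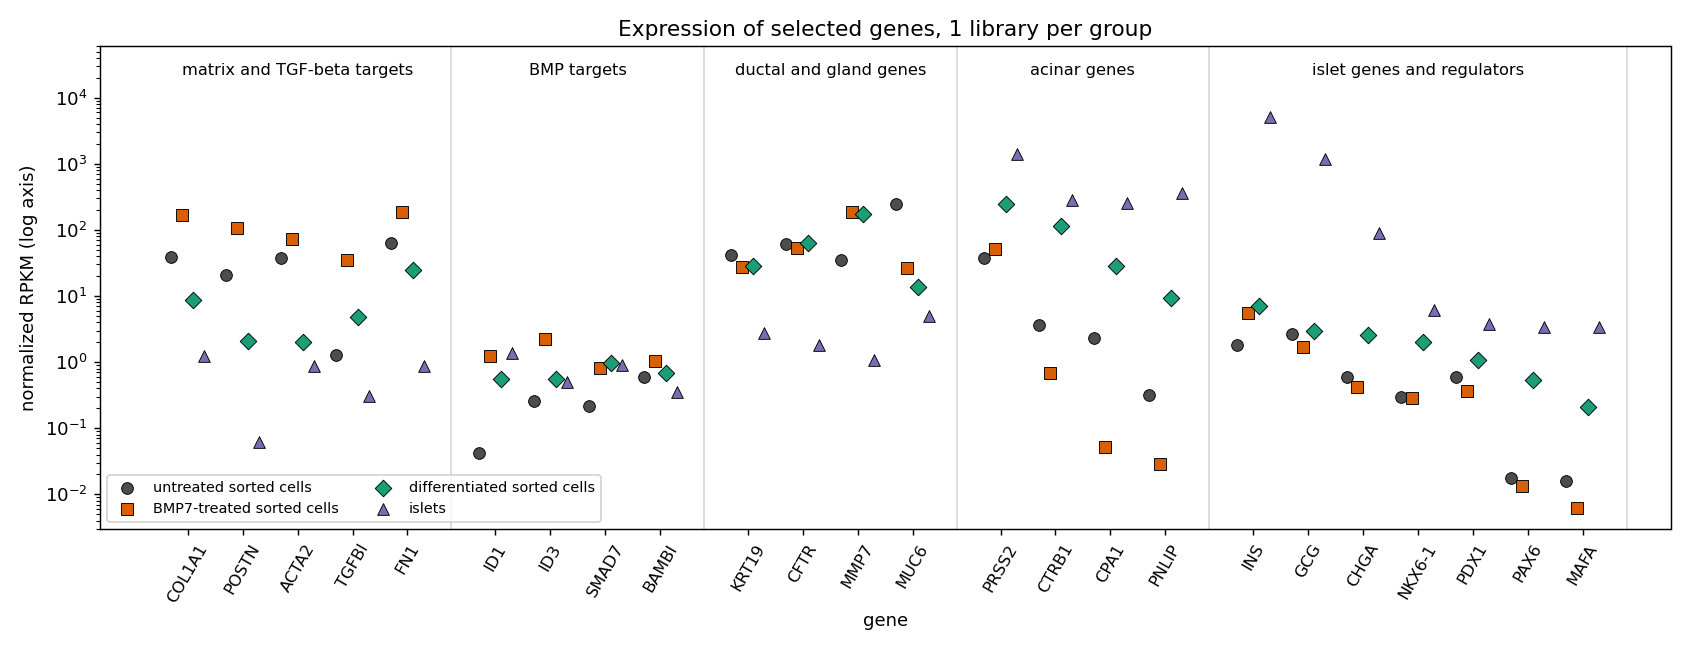
Normalized RPKM (log axis) of 24 genes in the 4 libraries, 1 point per library, with the genes grouped by kind and no error bars because each group is 1 library. COL1A1 goes from 39.03 in untreated to 168 in BMP7-treated and 8.80 RPKM in differentiated cells, and INS lies at 7.06 RPKM in differentiated cells against 5113 RPKM in islets.

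Islets were then set against untreated cells to show the distance between the sorted cells and endocrine tissue. The sources used here give no tissue culture, oxygen level or sort for the islets. Each difference between sorted cells and islets, here and below, may therefore also reflect handling, which cannot be separated from cell type. INS (insulin, chromosome 11, 2159779 to 2161341) was 2794-fold (2543 to 3078) higher, at 5113 against 1.83 RPKM. PIGR, an epithelial immunoglobulin transporter (chromosome 1, 206928518 to 206946466), was 228-fold (205 to 255) lower, at 0.394 against 89.8 RPKM. Of 6628 genes, 775 were at least 2-fold higher in islets and 604 lower, and 16 lists stood apart. The balance turned under upper quartile scaling, with 670 higher and 701 lower, and with totals that leave out mitochondrial, acinar and hormone genes, with 652 higher and 747 lower.

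All 24 hormone and granule genes were at least 2-fold higher (median log2 difference 5.30, percentile 100), GCG by 438-fold, SST by 266-fold (237 to 299), PPY by 881-fold, IAPP by 196-fold and CHGB by 692-fold. TTR, a transthyretin gene active in alpha cells, was 1298-fold (1129.7 to 1499) higher. INS-IGF2, at 595 RPKM in islets, overlaps INS. Beta cell genes (17 of 18 higher, median log2 difference 2.08, percentile 100) and endocrine transcription factors (12 of 13, median log2 difference 2.01, percentile 100) stood apart upward. G6PC2 and ABCC8 reached 30.1 and 31.3 RPKM, and NEUROD1 and MAFA 5.98 and 3.34 RPKM. In the same library all 26 acinar genes compared were at least 2-fold higher (median log2 difference 5.51, percentile 100). PNLIP, AMY2A, PLA2G1B and CELA3A were 1115-fold, 199.7-fold, 512-fold and 229-fold higher, and REG1A, at 137 against 60.97 RPKM, turned lower under quantile normalization. AMY2A and CELA3A have near-identical copies. Immediate early and heat shock genes were higher in 15 of 18 (median log2 difference 2.51, percentile 100). FOSB had 37.3 against 0.0314 RPKM, and the near-identical HSPA1A and HSPA1B had 247 and 248 RPKM. BMP targets were higher in 3 and lower in 2 of 7 (median log2 difference 0.91, percentile 98.54), with KLF10 14.9-fold higher and GREM1 76.1-fold lower.

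Ductal genes were lower in 20 of 22 members and higher in 0 (median log2 difference -2.38, percentile 0). CFTR, the chloride channel of duct cells, was 34.5-fold (33.3 to 35.8) lower. LYZ, FN1, the neutrophil chemokine CXCL5, OLFM4 and LCN2 were 96.1-fold (86.7 to 107) lower, 72.3-fold (69.7 to 75.1) lower, 492-fold (346 to 724) lower, 37.1-fold (35.1 to 39.2) lower and 31.7-fold (29.8 to 33.8) lower. DMBT1 was listed at 0 in islets, against 24.8 RPKM, and whether this 0 is a true absence of the transcript is open. Stellate and fibroblast genes (13 lower and 1 higher of 17, median log2 difference -2.76, percentile 0) had POSTN 334-fold and COL1A1 31.6-fold lower, and RGS5 34.1-fold (29.7 to 39.4) higher. Also apart downward, given with their median log2 differences, were TGF-beta targets (6 of 12 lower, 1 higher, -1.27), mesenchymal transition genes (9 of 12, -1.42), cell cycle genes (8 of 12, -1.18), YAP targets (8 of 10, -1.54), cholesterol synthesis genes (6 of 14, -0.90) and Notch genes (2 of 5, -0.94). NF-kB and cytokine genes (6 lower and 5 higher of 18, -0.84) and epithelial junction genes (1 lower and 1 higher of 13, -0.50) were so by their medians. Only their members at least 2-fold apart were nearly evenly split. The other 7 and 11 members lay within 2-fold, and most of the junction genes among them were lower, such as CDH1 at 9.10 against 16.3 RPKM. Not apart were progenitor genes (0.10), BMP receptors and ligands (0.10), hypoxia-induced genes (-0.05), unfolded protein response genes (0.59), mitochondrial genes (0.73) and ribosomal protein genes (0.15). Hypoxia-induced genes stood apart downward under each of the 4 other scalings. The unfolded protein response list stood apart with a pseudocount of 0.1, and the mitochondrial list under quantile normalization, where its median was -0.939. Both also did so without the RPKM minimum and against random lists not matched on expression.

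Differentiated cells were last set against islets, the comparison closest to the question of how far they had moved toward endocrine cells. All 24 hormone and granule genes remained at least 2-fold lower than in islets (median log2 difference -5.07, percentile 0), while complement, chemokine and ductal genes were higher. INS was 725-fold (665 to 791) lower, at 7.06 against 5113 RPKM. CFB was 472-fold (428 to 521) higher, and MMP7 (chromosome 11, 102520508 to 102530753) 164-fold (149 to 179.6) higher. Of 6909 genes, 739 were at least 2-fold higher in differentiated cells and 741 lower, and 17 lists stood apart.

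Lower were endocrine transcription factors (12 of 13, median log2 difference -1.76, percentile 0) and beta cell genes (17 of 18, median log2 difference -1.86, percentile 0). NKX6-1 was 3.04-fold lower, PAX6 6.30-fold, MAFA 15.9-fold (12.02 to 21.6) lower and NKX2-2 206-fold (88.1 to 635) lower. UCN3, a marker of mature beta cells, had 0.525 against 3.38 RPKM. G6PC2 had no read and was 2982-fold lower against the floor of 3 reads, with an interval reaching up to 0.0412% of its islet level. GCG, TTR, PPY, IAPP, CHGB and SST were 401-fold, 1324-fold, 1469.8-fold, 738-fold, 547-fold and 154-fold lower. Acinar genes were lower in 24 of 26 and higher in 1 (median log2 difference -3.26, percentile 0), from AMY2A at 153-fold (139 to 169.8) lower to REG1A at 2.21-fold (2.18 to 2.24) higher. AMY1C, a near-identical copy of AMY2A, was 94.6-fold lower. Immediate early and heat shock genes (14 of 18 lower, median log2 difference -1.51, percentile 0) and unfolded protein response genes (5 of 12, median log2 difference -0.75, percentile 1.16) stood apart downward, the latter not with a pseudocount of 5 or a minimum of 5 RPKM.

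Higher in differentiated cells were ductal genes (18 of 22, median log2 difference 1.90, percentile 100) and NF-kB and cytokine genes (11 of 18 higher, 2 lower, median log2 difference 2.01, percentile 100). The chemokines CXCL6 and CXCL5 were 658-fold (506 to 871) higher and 1196-fold (843 to 1761) higher. DUOX2 and DUOXA2, which form the dual oxidase of epithelia and lie next to each other on chromosome 15, were 618-fold (547 to 701) higher and 408-fold (296 to 580.1) higher. C3, LYZ, OLFM4, REG3A, UBD and PIGR were 109-fold, 95.6-fold, 70.6-fold, 69.6-fold, 74.2-fold and 96.5-fold higher. Epithelial junction genes (8 of 16, median log2 difference 1.04, percentile 100), TGF-beta targets (8 of 13, median log2 difference 1.40, percentile 100), progenitor genes (6 higher and 3 lower of 16, median log2 difference 0.42, percentile 99.43), Notch genes (2 of 5, median log2 difference 0.99, percentile 99.27), YAP targets (3 of 7, median log2 difference 0.92, percentile 99.28) and hypoxia-induced genes (6 of 19, median log2 difference 0.49, percentile 99.58) stood apart upward. Within the progenitor list the duct-associated factors SOX9 and ONECUT1 were 7.60-fold and 37.2-fold higher, and PDX1 and NKX6-1 lower. Mitochondrially encoded genes were higher in 11 of 13 (median log2 difference 1.82, percentile 99.89). Stellate and fibroblast genes (4 higher and 2 lower of 15, median log2 difference 0.55, percentile 99.2) lost their place with a pseudocount of 0.1 or no minimum. Mesenchymal transition genes (3 higher and 1 lower of 7, median log2 difference 0.85, percentile 98.58) lost theirs under 4 of 8 alternatives, and their median was -0.00932 without the minimum. Only 4 cell cycle genes were high enough to compare, with 0 at least 2-fold apart. BMP targets (-0.56), BMP receptors and ligands (0.20), cholesterol synthesis genes (-0.33) and ribosomal protein genes (-0.34) did not stand apart.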

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

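The test against counting intervals was chosen after the data were seen, all other alternatives before. With no replicates, no alternative leaves out a replicate. Values follow the order of the report, that is BMP7 against untreated, differentiated against BMP7-treated, differentiated against untreated, islets against untreated, and differentiated against islets. The 172, 528, 719, 1379 and 1480 genes at least 2-fold apart became 384, 1192, 1534, 2458 and 2565 with a pseudocount of 0.1, 51, 152, 168, 363 and 356 with a pseudocount of 5, and 86, 283, 336, 537 and 596 among genes with at least 5 RPKM. They became 28, 114, 131, 387 and 362 at 4-fold. These counts follow from the settings' construction, since a larger pseudocount shrinks folds and a higher minimum or threshold takes fewer genes. Counting intervals wholly beyond 2-fold, without a pseudocount, took 369, 1080, 1390, 2361 and 2371 genes, more because low genes are not shrunk. Taking no minimum left every total the same, which also follows from construction. With a pseudocount of 1, a gene below 1 RPKM in both libraries cannot be 2-fold apart. The 4 other scalings kept every total within 1.5 times. The 13, 14, 14, 16 and 17 lists standing apart became 7, 7, 7, 9 and 8 with the minimum of 5 RPKM, which leaves fewer lists with 5 members. The other alternatives kept these numbers within 1.5 times. Under quantile normalization, which gives the highest genes of all libraries the same values, log2 differences turned over for MT-ND2 (-0.305), MT-ATP8 (-0.124), MT-CO3 (-0.0818) and MT-CYB (-0.0712) in differentiated against BMP7-treated cells. They did so for MT-ND2 (-0.305), MT-ATP8 (-0.124) and MT-CO3 (-0.0818) against untreated cells, and for MT-ND2 (-0.100) and REG1A (-0.302) in islets against untreated cells. Only genes at least 2-fold apart as deposited were followed in this way. In islets against untreated cells the median of the whole mitochondrial list turned negative too, as given above. Without the minimum, mesenchymal transition genes in differentiated cells against islets had a median of -0.00932, through members below 1 RPKM. Calls of single lists were lost with a minimum of 5 RPKM for epithelial junction and hypoxia-induced genes in all 3 comparisons of the differentiated library, immediate early genes in differentiated against BMP7-treated cells, cholesterol synthesis genes in islets against untreated cells and mitochondrial genes after BMP7. Without a minimum, BMP targets and Notch genes lost theirs in islets against untreated cells. Lists that came to stand apart were NF-kB genes after BMP7 (minimum of 5 RPKM), ductal genes in differentiated against BMP7-treated cells (unmatched random lists), TGF-beta targets in differentiated against untreated cells (no minimum and unmatched random lists) and, against islets, BMP targets (pseudocount of 0.1) and BMP receptors and ligands (no minimum). The differentiated library, with 10242896 recovered reads outside mitochondrial genes against 28574676, 36993846 and 21355957 in the untreated, BMP7 and islet libraries, sets the depth limit. In it, 3 reads in a gene of 1 kb equal 0.0315 RPKM, against 0.00986 RPKM in the untreated library.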

Other observations

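The 4 lists in the first 2 paragraphs and all tests below were chosen after the data were seen, and some list members had already been named above, so they are not independent of it. A first version of the tests used hand-picked genes and 4 patterns, and the present ones use the fixed lists. An earlier form of the tests for fibroblasts after BMP7 took small differences as evidence against a larger share and was dropped, as counting intervals leave out variation between libraries. An earlier form of the tests on INS set beta cell genes against their untreated levels, and islet genes against the whole INS level. It argued against both explanations, and was dropped because high untreated levels hide a small share and only the increase needs a cause. Complement and acute phase genes were higher after BMP7 (5 higher and 2 lower of 19, median log2 difference 0.54, percentile 100) and higher again in differentiated against BMP7-treated cells (11 higher and 0 lower of 19, median log2 difference 1.26, percentile 100). They were also higher in differentiated cells than in islets (18 higher and 0 lower of 19, median log2 difference 2.87, percentile 100). C3, the central complement component, had 12.2, 49.7, 180.4 and 1.65 RPKM in untreated, BMP7-treated and differentiated cells and islets, CFB 8.43, 34.6, 202 and 0.429 RPKM, and SERPINA3 22.6, 36.4, 145 and 17.02 RPKM. The near-identical C4A and C4B had 10.8 and 10.7 RPKM in differentiated cells against 0.696 and 0.698 RPKM in untreated cells. CRP and SAA1, classical acute phase genes, did not follow, with 18.6, 21.9, 12.1 and 0.373 RPKM and 9.83, 10.5, 7.57 and 0 RPKM. Nuclear genes of oxidative phosphorylation did not follow the mitochondrially encoded ones in the differentiated library (0 higher and 0 lower of 23, median log2 difference -0.04, percentile 11.15, against BMP7-treated cells). Their median was below the random lists in differentiated against untreated cells (0 higher and 1 lower of 28, median log2 difference -0.30, percentile 0.19) and after BMP7 (0 higher and 0 lower of 27, median log2 difference -0.27, percentile 0.01).

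Mucin and gland secretory genes were lower after BMP7 (0 higher and 11 lower of 16, median log2 difference -1.68, percentile 0), and in differentiated against BMP7-treated cells went the other way (9 higher and 0 lower of 12, median log2 difference 1.58, percentile 99.95). Differentiated against untreated, they did not stand apart (3 higher and 7 lower of 16, median log2 difference -0.30, percentile 3.09). The members split. MUC6, MUC5B, AGR2 and DMBT1 had 13.5, 0.309, 0.488 and 0.779 RPKM in differentiated cells, below the 244, 3.59, 6.13 and 24.8 RPKM of untreated cells, whereas OLFM4, MUC1 and DUOX2 stood at 167, 29.1 and 85.2 RPKM against 87.7, 14.5 and 10.7 RPKM, and LYZ and MUC20 were level. Interferon response genes had a median above the random lists after BMP7 with no member 2-fold apart on the scale with the pseudocount (0 higher and 0 lower of 14, median log2 difference 0.40, percentile 99.99). IFIT1, IFIT3 and PSMB8 were lower, with 0.377 against 1.32, 1.41 against 2.66 and 2.70 against 3.25 RPKM, and the other compared members were higher. In differentiated against untreated cells this list did not stand apart (2 higher and 1 lower of 13, median log2 difference 0.06, percentile 43.47).

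Stellate and fibroblast genes were higher after BMP7 and lower after differentiation. A larger share of fibroblast or stellate cells in the BMP7 library would raise all their transcripts. Of 20 list members 14 lay wholly above 1 by counting intervals and 6 wholly below 1, of which 2 lay wholly below 0.5 (DCN and FBLN1). Without replicates this neither excludes nor supports a larger share. A difference in scaling would shift matched random lists alike, whereas the list's median lay 0.612 above theirs (SD of the random lists 0.1002), which argues against it. This is the same comparison by which the list was found to stand apart, so it is no separate evidence. In differentiated against BMP7-treated cells, 19 of 20 members lay wholly below 1 and 0 wholly above 1, which is consistent with a smaller share of fibroblast or stellate cells in that library, though the factors ran from no decrease for SFRP2 (ratio 1.18) and 1.73-fold for NOTCH3 to 51.7-fold for POSTN, wider than 1 common factor gives. A response of the cells themselves to BMP7 and to its removal stays open and was not tested. Neither the time in culture after the sort nor the oxygen level during BMP7 treatment is recorded.

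Acinar genes were higher in the differentiated than in the untreated library. RNA carried over from the islet library, which is rich in acinar transcripts, would set them at 1 common percentage of their islet level. The percentage ran from 0.652 for AMY2A to 221 for REG1A, a ratio of 339 over 19 genes, or 54.6 without the lowest and the highest. This ratio cannot decide, since it uses whole levels and untreated cells already differed. AMY2A and REG1A had 1.66 and 60.97 RPKM there, against 332 and 137 RPKM in islets. Whole levels do bound what carry-over can add, at 0.652% for AMY2A and 0.906% for CELA3B. CTRB1 and CTRB2 rose further, from 3.62 and 1.29 to 113 and 51.3 RPKM, against 279 and 104 RPKM in islets. This argues against carry-over as the cause of their rise. The larger mitochondrial share or another scaling difference is argued against by a list median of at least 2.08 under the 4 other scalings. A larger share of acinar cells is not excluded, since 26 of 26 members had intervals wholly above 1 and 0 wholly below 1, though the factors ran, low genes included, from 1.30 for AMY2A to 94.3 for SYCN. It may be acinar cells that outlasted the sort, or sorted cells that took up acinar expression in differentiation, which these libraries cannot separate.

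INS was 3.86-fold higher in the differentiated than in the untreated library, and the increase was 0.102% of its islet level. RNA of the islet library carried into the differentiated library would lift every abundant islet transcript to at least that percentage. By counting intervals 2 of 22 members of the hormone and beta cell lists stood below it, GAD2 with 1 read where 7.06 would be needed and G6PC2 with 0 where 9.14 would be. Most others were above it in untreated cells already, so their level says nothing on either explanation. More residual beta cells in the differentiated library would do the same for beta cell genes, of which 1 of 4 stood below it (G6PC2), and IAPP was 3.76-fold (2.86 to 5.03) lower than in untreated cells. These reads are too few to exclude either explanation, so both stay open, as does transcription of INS by the differentiated cells.

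In BMP7-treated cells INS was 3.01-fold (2.70 to 3.35) higher than in untreated cells, with MAFA at 0.00629 RPKM. P2RY1 had 0.230 RPKM in the untreated, 0.0471 in the BMP7 and 0.0374 RPKM in the differentiated library, although the cells were sorted for its protein. BHLHE40 and SKIL had their highest RPKM of the 4 libraries in differentiated cells, at 9.04 and 7.55, while CTGF had its highest after BMP7, at 51.6.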
